A study of Homo sapiens with 12 samples.

How the data were processed

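RNA of MDA-MB-231 cells was sequenced after transfection of 20 nM LNA with a lipid reagent and collection on day 2, with libraries made by the TruSeq RNA kit per the labels. The deposited values are raw counts of reads per gene, with 1 column per library for 12 libraries, and they carry no normalisation. The authors' processing notes list FastQC, STAR 2.6.0a, featureCounts and DESeq2 with the build hg38, without saying what each did. Strandedness and the handling of reads that map to several places are not given in the sources used here. The table held 52897 lines, of which 52859 genes were used. The lines of 12 genes with long exon lists (UBR4, ANKRD36, NEB, TTN, ABI3BP, ANK2, DST, SYNE1, NRCAM, PTK2, CACNA1C and UTY) were broken, with values out of their columns, and were left out with 26 fragments that held at most 0.141% of a library's counts. Genes on alternate loci or scaffolds (6108) were kept as separate genes and held at most 0.0845% of counts. The 24 mitochondrial genes used were tRNA and rRNA genes, and no mitochondrial mRNA was among them.

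Groups were taken from the labels: control, mtAsn-1, mtAsn-2 and mtLys LNA, with 3 libraries each. Total counts were 27067977, 31112975 and 18826253 for control, 20697370, 17978825 and 28314164 for mtAsn-1, 34832707, 30524246 and 31553676 for mtAsn-2, and 37708993, 34584704 and 27316004 for mtLys. Mitochondrial tRNA and rRNA genes held 0.881% to 1.23% of counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group (minimum count 10, minimum total 15), and robust quasi-likelihood F tests in 1 fit of all libraries, with Benjamini-Hochberg adjusted p under 0.05 within each comparison. This left 16051 genes and a common biological coefficient of variation of 0.0421. Log2 CPM used a prior count of 2. Standard errors (SE) were back-calculated as the absolute log2 fold change over the square root of its F statistic in the same fit. They are not standard errors given by the fit itself. SD is over the 3 libraries of a group. MT-TN had too few reads for that test, so rate ratios with 95% counting intervals and two-sided exact permutation tests of log2 CPM were used. A floor of 3 counts per library was worked out for reference and was not applied in these tests. Replicates were checked for copied libraries, and none was found (chi-square per gene at least 2.35).

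Before the data were examined, 28 gene lists, the comparisons, the alternatives and a rule for naming genes were fixed. The rule took the targets first, then the 6 largest rises and 6 largest falls per comparison (5 and 5 for the last 2 comparisons) among protein-coding genes with adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the groups' libraries. For genes shared by both asparagine LNAs it took the 6 rises and 6 falls with the largest smaller change, and for each list up to 2 rises and 2 falls with the smallest adjusted p. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on voom values, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated per list and with fry. Camera asks whether the genes of a list change more than other genes, and fry whether they change at all. The list of 13 mitochondrial mRNAs could not be tested, which left 27. Direct comparisons of each asparagine LNA with mtLys had been planned as parts of the count of genes shared by both, and were added as separate results after the data had been seen.

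Overlaps between comparisons that share the control libraries were set beside the product of list sizes over all tested genes and beside 20 simulations of unchanged groups. Each simulation redrew all libraries, controls included, at the mean control level with the spread seen between libraries of a group. Its comparisons shared the redrawn controls. The test was checked on simulated changes in 15776 genes, where 56%, 70%, 86% and 96% of genes changed by 1.25, 1.5, 2 and 4 fold were recovered and 11 of 165 calls were false. With lists, the shifted list was called and 1 of 20 unshifted lists was called too. Those lists held random genes drawn independently of each other, so the check does not cover lists whose genes are correlated. Alternatives were RLE factors, DESeq2 1.42.0, no filter or a stricter filter (at least 1 CPM in each library of a group and a mean log2 CPM of at least 2), a replicate block, the compared groups alone, factors without mitochondrial genes, and leaving out each library in turn. Thinning of libraries to the smallest total was added after the data had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.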

Results

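RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, after transfection with a locked nucleic acid (LNA). LNAs are short, chemically stabilised oligonucleotides that pair with a complementary RNA. The 12 libraries fell into 4 groups of 3: a control LNA, the mtAsn-1 and mtAsn-2 LNAs, which are 2 oligonucleotides against the mitochondrial asparagine tRNA, and an LNA against the mitochondrial lysine tRNA, mtLys. Cells received 20 nM of LNA and were collected on day 2. Total counts per library ranged from 17978825 (mtAsn-1, replicate 2) to 37708993 (mtLys, replicate 1). Replicates of a group correlated at 0.9925 to 0.9963 across genes in log2 CPM (counts scaled by library size), and 16051 genes were tested. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

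The targeted tRNA genes were examined first in every library. MT-TN, the asparagine tRNA gene (mitochondrial genome, 5657 to 5729, minus strand), had 3, 6 and 2 reads in the control libraries, 5, 2 and 2 with mtAsn-1, 1, 1 and 3 with mtAsn-2, and 4, 5 and 1 with mtLys. The ratio of MT-TN rates to control was 0.951 with mtAsn-1 (95% counting interval 0.348 to 2.52), 0.343 with mtAsn-2 (0.0933 to 1.07) and 0.707 with mtLys (0.269 to 1.83). Two-sided exact permutation tests of log2 CPM gave p = 1, 0.1 and 0.4 for these groups, and 3 libraries against 3 cannot go below 0.1. A change of MT-TN was therefore not detectable at this depth, and the gene does not check the labels. MT-TK, the lysine tRNA gene (mitochondrial genome, 8295 to 8364, plus strand), stood at 6.20 ± 0.514 CPM (SD, n = 3) in control, 7.86 ± 1.73 with mtAsn-1, 8.46 ± 1.78 with mtAsn-2 and 7.74 ± 0.487 with mtLys. By edgeR it was higher with mtAsn-2 (log2 fold change 0.44 ± 0.152, SE, adjusted p = 0.0205) and did not pass with mtAsn-1 (0.36 ± 0.162, adjusted p = 0.0748) or mtLys (0.32 ± 0.154, adjusted p = 0.0979). The MT-TK call with mtAsn-2 was lost without control replicate 2 (adjusted p = 0.0872) or 3 (0.0625) and without mtAsn-2 replicate 1 (0.0559) or 2 (0.0913). MT-TK passed with mtAsn-1 without mtAsn-1 replicate 1 (0.00857) or mtAsn-2 replicate 2 (0.0355) or 3 (0.0224), and with mtLys without mtAsn-1 replicate 1 (0.0489) or 3 (0.0434) or mtAsn-2 replicate 3 (0.0342). It also passed without the low-count filter (0.00492 with mtAsn-1, 0.0085 with mtLys) and in the compared libraries alone (0.0331 and 0.0102). MT-TK did not pass between mtAsn-1 and mtAsn-2 (adjusted p = 0.692) or between their mean and mtLys (0.664). The library chemistry captures polyadenylated RNA as a rule, so these reads need not reflect mature tRNA, and intervals cover counting error only.

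Of the nuclear genes for the matching mitochondrial aminoacyl-tRNA synthetases, NARS2 (asparagine) did not pass against control with any LNA: log2 fold changes were 0.15 ± 0.079 with mtAsn-1 (adjusted p = 0.134), 0.05 ± 0.075 with mtAsn-2 (0.643) and 0.05 ± 0.075 with mtLys (0.644). KARS1 (lysine, cytosolic and mitochondrial) fell with mtAsn-1 (-0.13 ± 0.044, adjusted p = 0.0152), a call lost without control replicate 2 (0.218) or mtAsn-1 replicate 3 (0.0569). KARS1 did not pass with mtAsn-2 (-0.08 ± 0.043, 0.149) or mtLys (-0.10 ± 0.044, 0.0571), where it passed without control replicate 1 (0.0326) or 3 (0.0204), under the stricter filter on low counts (0.0457) and with libraries thinned to the smallest total (0.0368). Between mtAsn-1 and mtAsn-2 (0.316) and between their mean and mtLys (0.965) KARS1 did not pass. None of the 13 mitochondrially encoded mRNAs was among the genes used here, so their levels were not analysed here.

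**Figure D1:**
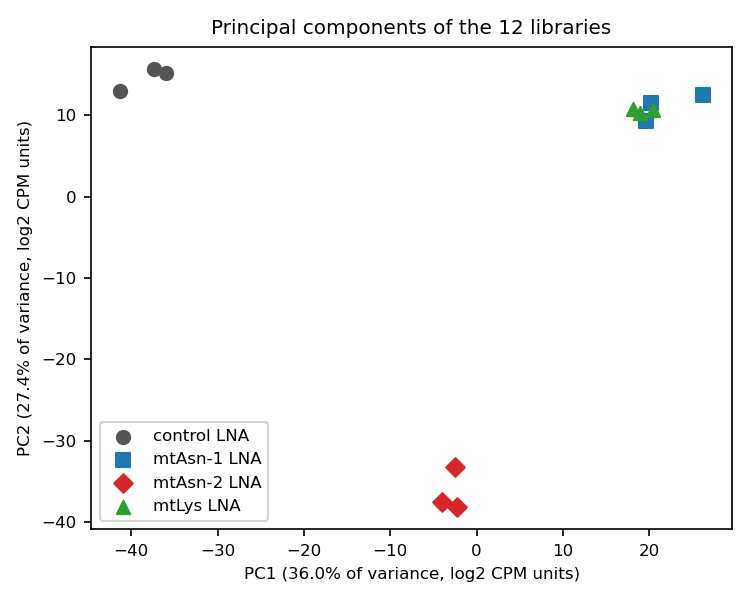
Principal components of the 12 libraries from log2 CPM of the 16051 tested genes; the first component holds 36.03% and the second 27.43% of the variance. Control libraries lie at the left, the 3 mtAsn-2 libraries at the bottom, and mtAsn-1 and mtLys libraries share the upper right.

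The first principal component parted the control libraries from the other groups, and the second parted mtAsn-2 from the rest, while mtAsn-1 and mtLys libraries lay close together on both. The third, with 8.04% of the variance, parted these groups. On it the mtAsn-1 libraries lay at 8.54, 27.4 (replicate 2) and 4.52, and the mtLys libraries at -10.72, -17.25 and -17.17. Genes named below that overlap another annotated gene on the opposite strand are uncertain, because neither the kit nor the counting is stated to keep strand. They are NARS2, KRT8, KRT18, NR4A1, EXOC4, FHIT, DNHD1, SHISAL1, CACNA2D1, SHMT2, CYP51A1, TNFAIP2, TGFBI, PFKM, LOX, ME1, ACSL4, SLC7A11, MTHFD2, AGBL3, MAT2A, FARS2, PDHA1, ACADVL, TP53INP1, ADSS1, CEMIP, SHANK2, COL5A1, OFD1, PPIC and HPSE. Cytosolic ribosomal protein genes, histone genes, FTL, KRT8, KRT18, CXCL1 and CXCL2 have near-identical copies that can share reads, and mitochondrial genes have copies in the nuclear genome. Coordinates are those of the hg38 build.

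The comparison of mtAsn-1 with control asked what an LNA against the asparagine tRNA changes in these cells. BMF, which encodes a pro-apoptotic BH3-only protein (chromosome 15, 40087890 to 40108879, minus strand), fell from 56.8 ± 3.35 CPM in control to 8.62 ± 1.65 with mtAsn-1 (n = 3 each, log2 fold change -2.75 ± 0.098, adjusted p = 5.98e-16). S100P, a calcium-binding protein gene (chromosome 4, 6693878 to 6697170, plus strand), fell from 18.1 ± 1.47 to 1.90 ± 0.278 CPM (-3.26 ± 0.133, 6.9e-17). The nuclear receptor gene NR4A1 (-2.27 ± 0.115, 5.43e-15), the stress-induced transcription factor gene ATF3 (-1.88 ± 0.14, 3.34e-10), the small GTPase gene RRAD (-1.95 ± 0.141) and ADM5 (-2.05 ± 0.136) also fell. EXOC4, an exocyst subunit gene (chromosome 7, 133253067 to 134067137, plus strand), rose from 15.4 ± 0.504 to 78.8 ± 4.76 CPM (2.36 ± 0.062, 3.07e-21). FHIT (2.09 ± 0.139), DNHD1 (2.08 ± 0.116), SHISAL1 (1.99 ± 0.154), the calcium channel subunit gene CACNA2D1 (1.98 ± 0.115) and the cytokine gene TNFSF15 (2.31 ± 0.551, 0.00746) rose as well.

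In total 3901 genes were higher and 3886 lower with mtAsn-1 than with control (edgeR, adjusted p under 0.05), of which 358 and 562 differed by at least 2-fold. A stricter filter on low counts, which tests fewer genes, gave 199 genes at least 2-fold different in place of 920. Among 31 tested ATF4 target and integrated stress response genes, 25 fell and 3 rose (25 and 3 adjusted over the list alone). For ATF4 targets, the camera adjusted p was 2.92e-09, and adjusted p = 0.382 with an estimated correlation. They included PHGDH, which starts serine synthesis (-1.21 ± 0.079), and SLC3A2, an amino acid transporter subunit (-0.95 ± 0.05), while SHMT2 rose (0.26 ± 0.039). Of 24 cholesterol synthesis and uptake genes, 17 fell and 1 rose (18 and 3 adjusted over the list alone), among them HMGCS1 (-0.74 ± 0.057) and CYP51A1 (-0.64 ± 0.054). For cholesterol genes, the camera adjusted p was 2.16e-05, and adjusted p = 0.53 with an estimated correlation. Of 22 NF-kB target and cytokine genes, 14 rose and 3 fell (16 and 4 adjusted over the list alone). For NF-kB targets, the camera adjusted p was 6.2e-04, and adjusted p = 0.545 with an estimated correlation. IL1B (1.94 ± 0.222) and the cyclooxygenase gene PTGS2 (1.55 ± 0.168) rose, and TNFAIP2 fell (-0.28 ± 0.051). Of 29 extracellular matrix and mesenchymal genes, 18 rose and 4 fell (19 and 4 adjusted over the list alone), with ITGA2 (0.82 ± 0.044) and TGFBI (0.72 ± 0.045) higher and COL1A1 (-0.72 ± 0.062) lower. For extracellular matrix genes, the camera adjusted p was 5.49e-05, and adjusted p = 0.505 with an estimated correlation. Of 22 immediate early genes, 12 fell and 4 rose (12 and 5 adjusted over the list alone). For immediate early genes, the camera adjusted p was 0.0224, and adjusted p = 0.545 with an estimated correlation. JUN (0.55 ± 0.06) and MYC (0.27 ± 0.044) were among those that rose. Interferon-stimulated genes were lower, 16 falling and 7 rising of 35 (16 and 7 adjusted over the list alone), with ISG15 (-1.09 ± 0.058) and IFITM1 (-1.12 ± 0.101) among them. For interferon-stimulated genes, the camera adjusted p was 0.04, and adjusted p = 0.545 with an estimated correlation. Of 39 cell cycle genes, 19 rose and 3 fell (19 and 3 adjusted over the list alone), MKI67 by 0.34 ± 0.049. For cell cycle genes, the camera adjusted p was 0.0258, and adjusted p = 0.654 with an estimated correlation.

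**Figure D2:**
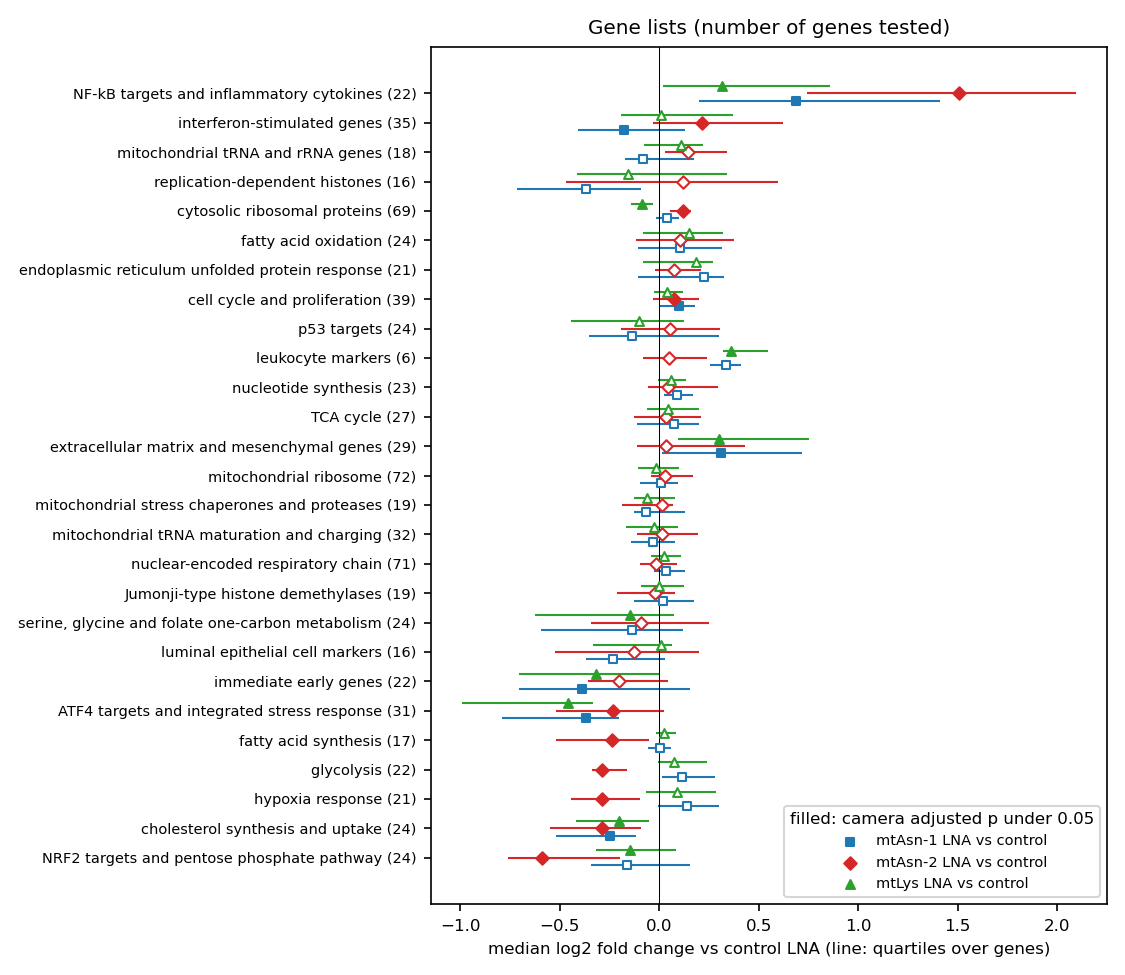
Median log2 fold change against control LNA of each gene list tested (number of tested genes in parentheses) for mtAsn-1, mtAsn-2 and mtLys; lines span the quartiles over genes and filled symbols mark a camera adjusted p under 0.05. ATF4 targets and cholesterol genes lie below 0 and NF-kB targets above 0 with all 3 LNAs, while glycolysis and hypoxia genes lie below 0 with mtAsn-2 and above 0 with the other LNAs.

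The comparison of mtAsn-2 with control put the same question with another oligonucleotide against the asparagine tRNA. Inflammatory mediators were among the largest rises: CSF2, a myeloid growth factor gene, went from 23.9 ± 3.58 to 121 ± 5.797 CPM (n = 3 each, 2.33 ± 0.225, adjusted p = 2.66e-05), and CXCL8, a neutrophil chemokine gene, from 9.22 ± 1.24 to 40.4 ± 3.20 CPM (2.12 ± 0.144, 9.47e-08). CSF3 (2.83 ± 0.156), CXCL1 (2.28 ± 0.151), CXCL2 (2.12 ± 0.14) and TNFSF15 (3.34 ± 0.469) rose too. BMF fell to 4.55 ± 0.625 CPM (-3.65 ± 0.1, 1.91e-18) and S100P to 4.54 ± 0.705 CPM (-2.001 ± 0.104). The water channel gene AQP1 (-2.33 ± 0.118), PCMTD1 (-1.98 ± 0.099) and ADM5 (-2.06 ± 0.126) fell as well.

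With mtAsn-2, 3862 genes were higher and 4337 lower than in control (edgeR), 408 and 555 of them by at least 2-fold (963 in all, and 223 under the stricter filter). The higher and lower genes numbered 4268 and 3955 without a filter, and 4072 and 4052 in the compared groups alone. Of 22 NF-kB target genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone), including TRAF1 (1.72 ± 0.075) and NFKB2 (0.95 ± 0.046). For NF-kB targets, the camera adjusted p was 1.76e-15, and adjusted p = 0.169 with an estimated correlation. Of 24 NRF2 target and pentose phosphate genes, 19 fell and 1 rose (19 and 1 adjusted over the list alone), among them the quinone reductase gene NQO1 (-1.49 ± 0.047) and TXNRD1 (-0.84 ± 0.041). For NRF2 targets, the camera adjusted p was 9.63e-08, and adjusted p = 0.0915 with an estimated correlation. Glycolysis genes fell, 17 of 22 with 1 rising (17 and 1 adjusted over the list alone), such as PKM (-0.64 ± 0.038) and the glucose transporter gene SLC2A3 (-0.89 ± 0.058), whereas PFKM rose (0.53 ± 0.041). For glycolysis genes, the camera adjusted p was 4.66e-05, and adjusted p = 0.52 with an estimated correlation. Of 21 hypoxia response genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone), including EGLN3 (-1.29 ± 0.067) and LOX (-1.14 ± 0.07). For hypoxia genes, the camera adjusted p was 4.22e-04, and adjusted p = 0.536 with an estimated correlation. Cholesterol genes fell, 17 of 24 with 0 rising (17 and 0 adjusted over the list alone), for example MSMO1 (-0.91 ± 0.05) and INSIG1 (-0.64 ± 0.038). For cholesterol genes, the camera adjusted p was 1.06e-05, and adjusted p = 0.524 with an estimated correlation. Of 17 fatty acid synthesis genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone), with ME1 (-0.92 ± 0.059) and ACSL4 (-0.65 ± 0.044) lower. For fatty acid synthesis genes, the camera adjusted p was 0.0107, and adjusted p = 0.536 with an estimated correlation. Of 31 ATF4 targets, 18 fell and 7 rose (19 and 7 adjusted over the list alone); the cystine transporter gene SLC7A11 fell (-0.87 ± 0.047) and MTHFD2 rose (0.46 ± 0.051). For ATF4 targets, the camera adjusted p was 0.00878, and adjusted p = 0.623 with an estimated correlation. Interferon-stimulated genes were higher, 21 rising and 5 falling of 35 (22 and 6 adjusted over the list alone), with OAS3 up by 0.78 ± 0.05 and IFITM1 at -0.86 ± 0.092. For interferon-stimulated genes, the camera adjusted p was 0.00124, and adjusted p = 0.536 with an estimated correlation. Of 69 cytosolic ribosomal protein genes, 42 rose and 1 fell (44 and 2 adjusted over the list alone), by small amounts such as 0.36 ± 0.035 for RPS3. For ribosomal protein genes, the camera adjusted p was 2.54e-06, and adjusted p = 0.664 with an estimated correlation. Cell cycle genes rose, 16 of 39 with 4 falling (16 and 4 adjusted over the list alone). For cell cycle genes, the camera adjusted p was 0.0334, and adjusted p = 0.664 with an estimated correlation.

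The comparison of mtLys with control tested an LNA against another mitochondrial tRNA. BMF fell to 10.1 ± 0.788 CPM (-2.50 ± 0.09, adjusted p = 5.39e-16, n = 3 each), and NUPR1, a stress-induced transcription regulator gene, fell from 15.7 ± 0.357 to 3.23 ± 0.374 CPM (-2.29 ± 0.12, 2.14e-14). NR4A1 (-2.29 ± 0.106), ATF3 (-2.12 ± 0.133), ADM5 (-2.02 ± 0.126) and AGBL3 (-1.84 ± 0.115) fell. EXOC4 rose to 77.7 ± 5.10 CPM (2.34 ± 0.061, 2.4e-21), and TNFSF15 (2.59 ± 0.506), CACNA2D1 (2.03 ± 0.109), FHIT (1.94 ± 0.135), DNHD1 (1.85 ± 0.114) and the type IV collagen gene COL4A5 (1.82 ± 0.077) rose.

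With mtLys, 3943 genes were higher and 3842 lower than in control (edgeR), 405 and 504 of them by at least 2-fold (909 in all, and 172 under the stricter filter). Of 31 ATF4 targets, 27 fell and 1 rose (27 and 1 adjusted over the list alone), with PHGDH at -1.56 ± 0.077 and SLC3A2 at -1.02 ± 0.05. For ATF4 targets, the camera adjusted p was 7.65e-16, and adjusted p = 0.0948 with an estimated correlation. Of 29 extracellular matrix genes, 20 rose and 2 fell (20 and 3 adjusted over the list alone), ITGA2 by 0.86 ± 0.044 and COL4A1 by 0.83 ± 0.043. For extracellular matrix genes, the camera adjusted p was 8.85e-07, and adjusted p = 0.233 with an estimated correlation. Cholesterol genes fell, 15 of 24 with 3 rising (17 and 3 adjusted over the list alone), HMGCS1 among them (-0.64 ± 0.055). For cholesterol genes, the camera adjusted p was 3.72e-04, and adjusted p = 0.494 with an estimated correlation. Of 24 serine, glycine and folate genes, 9 fell and 4 rose (9 and 4 adjusted over the list alone), and MAT2A, which makes S-adenosylmethionine, was lower by a log2 fold change of -0.98 ± 0.045. For serine, glycine and folate genes, the camera adjusted p was 0.0264, and adjusted p = 0.233 with an estimated correlation. Immediate early genes fell, 13 of 22 with 3 rising (13 and 3 adjusted over the list alone). For immediate early genes, the camera adjusted p was 0.00198, and adjusted p = 0.54 with an estimated correlation. Of 24 NRF2 targets, 12 fell and 3 rose (12 and 3 adjusted over the list alone), with NQO1 at -1.05 ± 0.046 and the ferritin gene FTL at -0.78 ± 0.04. For NRF2 targets, the camera adjusted p was 0.0189, and adjusted p = 0.415 with an estimated correlation. Of 22 NF-kB targets, 10 rose and 1 fell (10 and 1 adjusted over the list alone). For NF-kB targets, the camera adjusted p was 0.0264, and adjusted p = 0.763 with an estimated correlation. Of 69 cytosolic ribosomal protein genes, 29 fell and 1 rose (29 and 1 adjusted over the list alone), RPL12 by -0.46 ± 0.041. For ribosomal protein genes, the camera adjusted p was 3.72e-04, and adjusted p = 0.763 with an estimated correlation. Of the 6 leukocyte marker genes that could be tested, 3 rose and 0 fell (5 and 0 adjusted over the list alone); LAPTM5 (0.60 ± 0.039) was at 139 ± 1.95 CPM in control and 210 ± 7.12 with mtLys. For leukocyte markers, the camera adjusted p was 0.0275, and adjusted p = 0.233 with an estimated correlation.

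Several lists fixed in advance were not called by camera against control with any of the 3 LNAs. They covered the nuclear-encoded respiratory chain (adjusted p = 0.0902 with mtAsn-1, 0.942 with mtAsn-2 and 0.268 with mtLys), the mitochondrial ribosome (0.711, 0.0858 and 0.821), mitochondrial tRNA maturation and charging (0.732, 0.413 and 0.641) and mitochondrial tRNA and rRNA genes (0.732, 0.144 and 0.44). The TCA cycle (0.165, 0.47 and 0.138), fatty acid oxidation (0.132, 0.18 and 0.0947), nucleotide synthesis (0.114, 0.115 and 0.138) and mitochondrial chaperones and proteases (0.482, 0.68 and 0.274) were not called either. Nor were the endoplasmic reticulum unfolded protein response (0.0553, 0.18 and 0.0998), p53 targets (0.141, 0.68 and 0.0998), Jumonji-type histone demethylases (0.482, 0.68 and 0.761), replication-dependent histones (0.16, 0.383 and 0.821) and luminal epithelial markers (0.0902, 0.161 and 0.669). By fry, fatty acid oxidation genes were higher with mtAsn-1, mtAsn-2 and mtLys (adjusted p = 0.00408, 0.0216 and 0.00167). TCA cycle (0.00331 and 0.00218) and endoplasmic reticulum genes (0.00194 and 0.00665) were higher with mtAsn-1 and mtLys, and p53 targets lower (0.0017 and 2e-04). Fry did not call mitochondrial tRNA maturation and charging, mitochondrial tRNA and rRNA genes or Jumonji-type demethylases with any LNA. Each other list was called with at least 1. Single members did change: the complex I subunit gene NDUFA10 rose with mtAsn-1 (0.72 ± 0.055), mtAsn-2 (0.48 ± 0.054) and mtLys (0.68 ± 0.053), and the phenylalanyl-tRNA synthetase gene FARS2 rose by 1.44 ± 0.097, 0.86 ± 0.097 and 1.40 ± 0.093. The pyruvate dehydrogenase subunit gene PDHA1 rose (0.61 ± 0.051, 0.57 ± 0.049 and 0.54 ± 0.049) and so did the fatty acid oxidation gene ACADVL (0.80 ± 0.05, 0.63 ± 0.05 and 0.78 ± 0.05). KDM7A fell (-0.77 ± 0.144, -1.68 ± 0.148 and -1.21 ± 0.141), as did TP53INP1 (-0.87 ± 0.069, -1.19 ± 0.067 and -0.91 ± 0.065) and the keratin gene KRT8 (-0.69 ± 0.038, -1.12 ± 0.038 and -0.58 ± 0.038). Over the 162 list tests of the 6 comparisons fixed in advance, the median, the mean and the camera direction differed in sign in 16, of which 0 were called.

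The genes that both asparagine LNAs changed against control were compared next. BMF, S100P and ADM5 fell with both, as did AQP1 (8.98 ± 0.63 CPM in control, 2.55 ± 0.284 with mtAsn-1 and 1.79 ± 0.152 with mtAsn-2), ADSS1 (-1.77 ± 0.133 and -1.67 ± 0.12) and TXNIP, a thioredoxin-interacting protein gene that restrains glucose uptake (-1.56 ± 0.098 and -1.46 ± 0.095). The glycosyltransferase gene EXTL2 rose from 10.3 ± 0.79 CPM to 28.9 ± 0.382 with mtAsn-1 and 33.9 ± 1.73 with mtAsn-2. TNFSF15, CACNA2D1, PTGS2 and CXCL1 also rose with both. In all, 1988 genes rose and 2372 fell with both LNAs, where independent lists of those sizes would share 939 and 1050, and 760 genes moved in opposite directions (1989 for independent lists). Across genes the fold changes correlated at 0.592 with covariance 0.166. In 20 simulations of unchanged groups with shared, redrawn controls the means were 0.522 and 0.0209, so the covariances differed by 0.145. The simulations gave at most 1 gene rising with both. Control libraries were too few to divide, so part of the excess may come from their sharing.

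Set against mtLys, the same overlap was larger for mtAsn-1. The genes rising with both mtAsn-1 and mtLys numbered 3171 and those falling 3072 (958 and 930 for independent lists), 19 moved in opposite directions, and the fold changes correlated at 0.863 with covariance 0.235 (simulated 0.514 and 0.0206, a covariance difference of 0.215). For mtAsn-2 and mtLys, 1992 genes rose and 2314 fell with both (949 and 1038 for independent lists), 762 moved in opposite directions, and the correlation was 0.605 with covariance 0.164 (simulated 0.565 and 0.0205, a difference of 0.144). Genes are not independent replicates in these correlations.

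**Figure D3:**
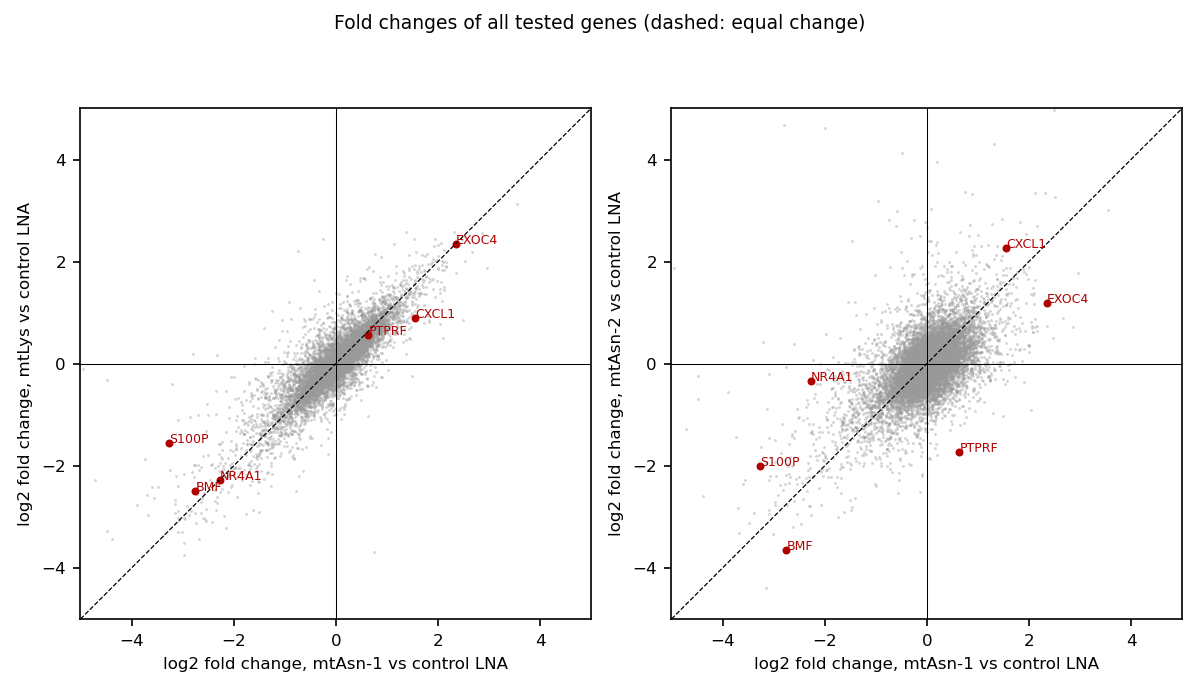
Log2 fold change against control LNA of the tested genes with mtAsn-1 (x axes) and with mtLys (left) or mtAsn-2 (right); points are genes, the dashed line marks equal change, and 1 gene lies outside the axes of each panel. Points lie closer to the line at the left (correlation 0.863) than at the right (0.592); PTPRF fell with mtAsn-2.

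The mean of both asparagine LNAs was compared with control to average over the oligonucleotides. BMF (-3.20 ± 0.079), S100P (-2.63 ± 0.097), AQP1 (-2.07 ± 0.099), ADM5 (-2.05 ± 0.108), ADSS1 (-1.72 ± 0.105) and the water and glycerol channel gene AQP3 (-1.58 ± 0.093) had the largest falls under the naming rule, and TNFSF15 (2.82 ± 0.467), CSF3 (2.15 ± 0.155), CXCL1 (1.91 ± 0.144), CACNA2D1 (1.82 ± 0.103), CXCL8 (1.80 ± 0.135) and DNHD1 (1.79 ± 0.105) the largest rises. By edgeR 3806 genes were higher and 4236 lower, 262 and 483 of them by at least 2-fold (745 in all, and 139 under the stricter filter). Cholesterol genes fell, 20 of 24 with 1 rising (21 and 1 adjusted over the list alone; camera adjusted p = 6.4e-07, and adjusted p = 0.347 with an estimated correlation), and 21 of 31 ATF4 targets fell with 2 rising (21 and 3 adjusted over the list alone; camera 6.4e-07, and adjusted p = 0.284 with an estimated correlation). Of 22 NF-kB targets, 21 rose and 1 fell (21 and 1 adjusted over the list alone). For NF-kB targets, the camera adjusted p was 1.84e-11, and adjusted p = 0.284 with an estimated correlation. NRF2 targets fell, 17 of 24 with 2 rising (17 and 2 adjusted over the list alone). For NRF2 targets, the camera adjusted p was 2.64e-05, and adjusted p = 0.284 with an estimated correlation. Cytosolic ribosomal protein genes rose, 32 of 69 with 3 falling (33 and 3 adjusted over the list alone; camera 1.51e-04, and adjusted p = 0.718 with an estimated correlation), as did 15 of 29 extracellular matrix genes with 3 falling (15 and 3 adjusted over the list alone; camera 0.00248, and adjusted p = 0.503 with an estimated correlation) and 20 of 39 cell cycle genes with 1 falling (21 and 2 adjusted over the list alone; camera 0.0095, and adjusted p = 0.718 with an estimated correlation). Immediate early genes fell, 12 of 22 with 3 rising (13 and 3 adjusted over the list alone). For immediate early genes, the camera adjusted p was 0.0439, and adjusted p = 0.718 with an estimated correlation. Of the lists called in this mean, NRF2 targets (adjusted p = 0.114) and ribosomal protein genes (0.0902) were not called with mtAsn-1 taken singly. Immediate early genes (0.305) and extracellular matrix genes (0.144) were not called with mtAsn-2. Tested directly between the asparagine LNAs, these 4 lists differed by camera (adjusted p = 7.47e-06, 0.00158, 0.0113 and 0.00928) and did not with an estimated correlation (adjusted p = 0.108, 0.698, 0.533 and 0.365).

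The asparagine LNAs were then compared directly with the lysine LNA, which leaves the control libraries out of the contrast. The chemokine genes CXCL2 (1.30 ± 0.126, adjusted p = 1.2e-08), CXCL8 (1.08 ± 0.119) and CXCL1 (1.02 ± 0.122) were higher with the asparagine LNAs, as were NUPR1 (1.17 ± 0.119) and PTGS2 (0.81 ± 0.12). NUPR1 was below control with each LNA. It stood at 15.7 ± 0.357 CPM in control, 5.65 ± 1.65 with mtAsn-1, 9.57 ± 0.202 with mtAsn-2 and 3.23 ± 0.374 with mtLys. AQP1 (-1.53 ± 0.101, 2.29e-12), the hyaluronan-binding protein gene CEMIP (-1.32 ± 0.071), AQP3 (-1.15 ± 0.093), the inhibin subunit gene INHBB (-1.15 ± 0.095) and SHANK2 (-1.10 ± 0.07) were lower. CEMIP stood at 28.97 ± 0.608 CPM in control, 18.4 ± 1.71 with mtAsn-1, 19.7 ± 1.20 with mtAsn-2 and 47.7 ± 6.78 with mtLys (n = 3 each). SHANK2 stood at 8.92 ± 1.03 CPM in control, 16.6 ± 1.38 with mtAsn-1, 5.64 ± 0.358 with mtAsn-2 and 20.6 ± 1.20 with mtLys, so its mean covered unlike levels: against control it was higher with mtAsn-1 (0.91, adjusted p = 4.08e-09) and lower with mtAsn-2 (-0.65, 4.27e-06). In total 1893 genes were higher and 2811 lower (edgeR), 49 and 103 by at least 2-fold. The latter, 152 in all, were 19 under the stricter filter, 94 by DESeq2 and 254 without a filter. Genes called the same way against control by both asparagine LNAs, and the same way against mtLys by both, numbered 188, of which 60 were higher and 128 lower. That count was 124 without mtAsn-1 replicate 2, 110 without mtLys replicate 2 and 108 without mtLys replicate 3. The 60 higher genes became 33 and 30 without mtAsn-1 replicates 1 and 2, and 38, 26 and 30 without mtLys replicates 1, 2 and 3. The 128 lower genes became 84 and 78 without mtLys replicates 2 and 3.

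Lists also differed between the mean of both asparagine LNAs and the lysine LNA. Of 69 cytosolic ribosomal protein genes, 63 were higher and 1 lower in that mean (65 and 1 adjusted over the list alone), RPL12 by 0.33 ± 0.036. For ribosomal protein genes, the camera adjusted p was 6.14e-27, and adjusted p = 0.164 with an estimated correlation. NF-kB targets were higher, 20 of 22 with 0 lower (21 and 0 adjusted over the list alone; camera 7.15e-18, and adjusted p = 0.123 with an estimated correlation), and so were 23 of 31 ATF4 targets with 2 lower (24 and 2 adjusted over the list alone; camera 5.07e-14, and adjusted p = 0.123 with an estimated correlation), such as MTHFD2 (0.51 ± 0.046) and PHGDH (0.75 ± 0.071). Glycolysis genes were lower, 15 of 22 with 1 higher (16 and 1 adjusted over the list alone; camera 3.66e-06, and adjusted p = 0.164 with an estimated correlation), as were 14 of 21 hypoxia genes with 0 higher (15 and 0 adjusted over the list alone; camera 3.66e-06, and adjusted p = 0.18 with an estimated correlation) and 12 of 17 fatty acid synthesis genes with 1 higher (13 and 1 adjusted over the list alone; camera 2.92e-05, and adjusted p = 0.164 with an estimated correlation). Extracellular matrix genes were lower too, 12 of 29 with 1 higher (14 and 3 adjusted over the list alone), with COL5A1 at -0.76 ± 0.036 and COL4A1 at -0.54 ± 0.036. For extracellular matrix genes, the camera adjusted p was 1.76e-04, and adjusted p = 0.164 with an estimated correlation. Luminal markers were lower, 8 of 16 with 2 higher (8 and 2 adjusted over the list alone), AGR2 by -0.89 ± 0.057. For luminal markers, the camera adjusted p was 0.018, and adjusted p = 0.288 with an estimated correlation. NRF2 targets (11 of 24 lower, 2 higher; 12 and 2 adjusted over the list alone; camera 0.0032, and adjusted p = 0.164 with an estimated correlation) and cholesterol genes (8 of 24 lower, 1 higher; 9 and 1 adjusted over the list alone; camera 0.027, and adjusted p = 0.567 with an estimated correlation) were lower. Higher lists were immediate early genes (9 of 22, 3 lower; 9 and 3 adjusted over the list alone; camera 0.00497, and adjusted p = 0.419 with an estimated correlation) and the mitochondrial ribosome (12 of 72, 1 lower; 11 and 1 adjusted over the list alone; camera 0.00966, and adjusted p = 0.565 with an estimated correlation). So were serine, glycine and folate genes (9 of 24, 3 lower; 9 and 4 adjusted over the list alone; camera 0.013, and adjusted p = 0.164 with an estimated correlation), p53 targets (7 of 24, 0 lower; 7 and 0 adjusted over the list alone; camera 0.0159, and adjusted p = 0.164 with an estimated correlation) and cell cycle genes (12 of 39, 5 lower; 13 and 5 adjusted over the list alone; camera 0.018, and adjusted p = 0.675 with an estimated correlation). Across all 15 lists called in this comparison, 0 held with an estimated correlation, where 7 had an unadjusted p under 0.05.

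Each asparagine LNA was also set against mtLys, in comparisons made separate results after the data had been seen. NRF2 targets were higher with mtAsn-1, 5 of 24 with 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.0154, and adjusted p = 0.365 with an estimated correlation), and lower with mtAsn-2, 16 with 1 higher (16 and 1 adjusted over the list alone; camera 7.18e-05, and adjusted p = 0.124 with an estimated correlation). Interferon-stimulated genes were lower with mtAsn-1, 13 of 35 with 0 higher (18 and 0 adjusted over the list alone; camera 7.19e-13, and adjusted p = 0.109 with an estimated correlation), and higher with mtAsn-2, 19 with 4 lower (19 and 4 adjusted over the list alone; camera 1.56e-04, and adjusted p = 0.22 with an estimated correlation). Glycolysis (camera adjusted p = 2.1e-08 with mtAsn-2 and 0.164 with mtAsn-1), hypoxia (6.71e-08 and 0.726), fatty acid synthesis (1.06e-04 and 0.101) and immediate early genes (0.00544 and 0.192) were called with mtAsn-2 and not with mtAsn-1. With an estimated correlation the mtAsn-2 values were adjusted p = 0.124, 0.196, 0.196 and 0.402. Adjusted over the list alone, mtAsn-2 gave 19 of 22 glycolysis genes lower and 1 higher, 17 of 21 hypoxia genes lower and 0 higher, 13 of 17 fatty acid synthesis genes lower and 1 higher, and 12 of 22 immediate early genes higher and 4 lower. These 4 lists and NRF2 targets also differed by camera between mtAsn-1 and mtAsn-2 directly (4.78e-10, 2.96e-08, 0.00174, 0.0113 and 7.47e-06), and not with an estimated correlation (adjusted p = 0.108, 0.21, 0.304, 0.533 and 0.108). The mitochondrial ribosome (camera adjusted p = 0.0209 with mtAsn-2 and 0.164 with mtAsn-1) and p53 targets (0.0239 and 0.234) were called with mtAsn-2 and not with mtAsn-1. With an estimated correlation the mtAsn-2 values were adjusted p = 0.571 and 0.205, and adjusted over the list alone 19 of 72 and 11 of 24 genes were higher, 5 and 4 lower. Cholesterol genes (0.0232 with mtAsn-1 and 0.141 with mtAsn-2), cell cycle genes (0.00193 and 0.152) and luminal markers (0.00978 and 0.145) were called with mtAsn-1 and not with mtAsn-2. With an estimated correlation the mtAsn-1 values were adjusted p = 0.553, 0.553 and 0.365, and adjusted over the list alone 1 of 24, 12 of 39 and 1 of 16 genes were higher, 3, 1 and 6 lower. For these 5 lists the direct test between the asparagine LNAs did not pass (0.0908, 0.0728, 0.699, 0.997 and 0.962), so a difference between the LNAs was not shown. MTHFD2 was higher than with mtLys under mtAsn-2 (0.87, adjusted p = 4.31e-14), did not pass under mtAsn-1 (0.16, 0.091), and differed between the asparagine LNAs (-0.71, 6.44e-12).

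The 2 asparagine LNAs were compared with each other to see how far oligonucleotides against the same tRNA differ. PTPRF, a receptor tyrosine phosphatase gene (chromosome 1, 43522238 to 43623672, plus strand), stood at 462 ± 36.2 CPM with mtAsn-1, 88.9 ± 1.98 with mtAsn-2 and 296 ± 21.8 in control (mtAsn-1 against mtAsn-2 2.38 ± 0.056, adjusted p = 1.87e-19, n = 3 each). OFD1 (1.98 ± 0.082), the cyclophilin gene PPIC (1.93 ± 0.084) and the heparanase gene HPSE (1.90 ± 0.069) were higher with mtAsn-1 than with mtAsn-2. NR4A1 (-1.93 ± 0.115), RRAD (-1.84 ± 0.139), the histone gene H2AC6 (-1.73 ± 0.148), PTPRH (-1.69 ± 0.144) and UNC13A (-1.51 ± 0.147) were lower. By edgeR 3949 genes were higher and 3516 lower, 347 and 340 by at least 2-fold (687 in all, and 186 under the stricter filter). Without a filter 3521 were higher and 3823 lower.

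Between these LNAs, 19 of 22 glycolysis genes were higher with mtAsn-1 and 1 lower (19 and 1 adjusted over the list alone), PGK1 by 0.54 ± 0.045. For glycolysis genes, the camera adjusted p was 4.78e-10, and adjusted p = 0.108 with an estimated correlation. Hypoxia genes were higher, 18 of 21 with 1 lower (19 and 1 adjusted over the list alone; camera 2.96e-08, and adjusted p = 0.21 with an estimated correlation), as were 14 of 24 NRF2 targets with 0 lower (14 and 0 adjusted over the list alone; camera 7.47e-06, and adjusted p = 0.108 with an estimated correlation), SLC7A11 by 1.08 ± 0.048. Interferon-stimulated genes were lower with mtAsn-1, 30 of 35 with 2 higher (30 and 2 adjusted over the list alone), with OAS3 at -0.86 ± 0.051 and IFI6 at -0.89 ± 0.073. For interferon-stimulated genes, the camera adjusted p was 4.15e-10, and adjusted p = 0.108 with an estimated correlation. NF-kB targets were lower, 20 of 22 with 0 higher (20 and 0 adjusted over the list alone; camera 7.38e-11, and adjusted p = 0.19 with an estimated correlation), RELB by -1.20 ± 0.061, and ATF4 targets were lower, 21 of 31 with 3 higher (22 and 4 adjusted over the list alone; camera 3.04e-05, and adjusted p = 0.272 with an estimated correlation). Histone genes were lower, 5 of 16 with 0 higher (5 and 0 adjusted over the list alone). For histone genes, the camera adjusted p was 0.0208, and adjusted p = 0.365 with an estimated correlation. Immediate early genes (13 of 22 lower, 4 higher; 14 and 4 adjusted over the list alone; camera 0.0113, and adjusted p = 0.533 with an estimated correlation) and cytosolic ribosomal protein genes (23 of 69 lower, 2 higher; 23 and 2 adjusted over the list alone; camera 0.00158, and adjusted p = 0.698 with an estimated correlation) were lower with mtAsn-1. Fatty acid synthesis genes (10 of 17 higher, 2 lower; 10 and 2 adjusted over the list alone; camera 0.00174, and adjusted p = 0.304 with an estimated correlation) and extracellular matrix genes (15 of 29 higher, 5 lower; 15 and 6 adjusted over the list alone; camera 0.00928, and adjusted p = 0.365 with an estimated correlation) were higher.

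**Figure D4:**
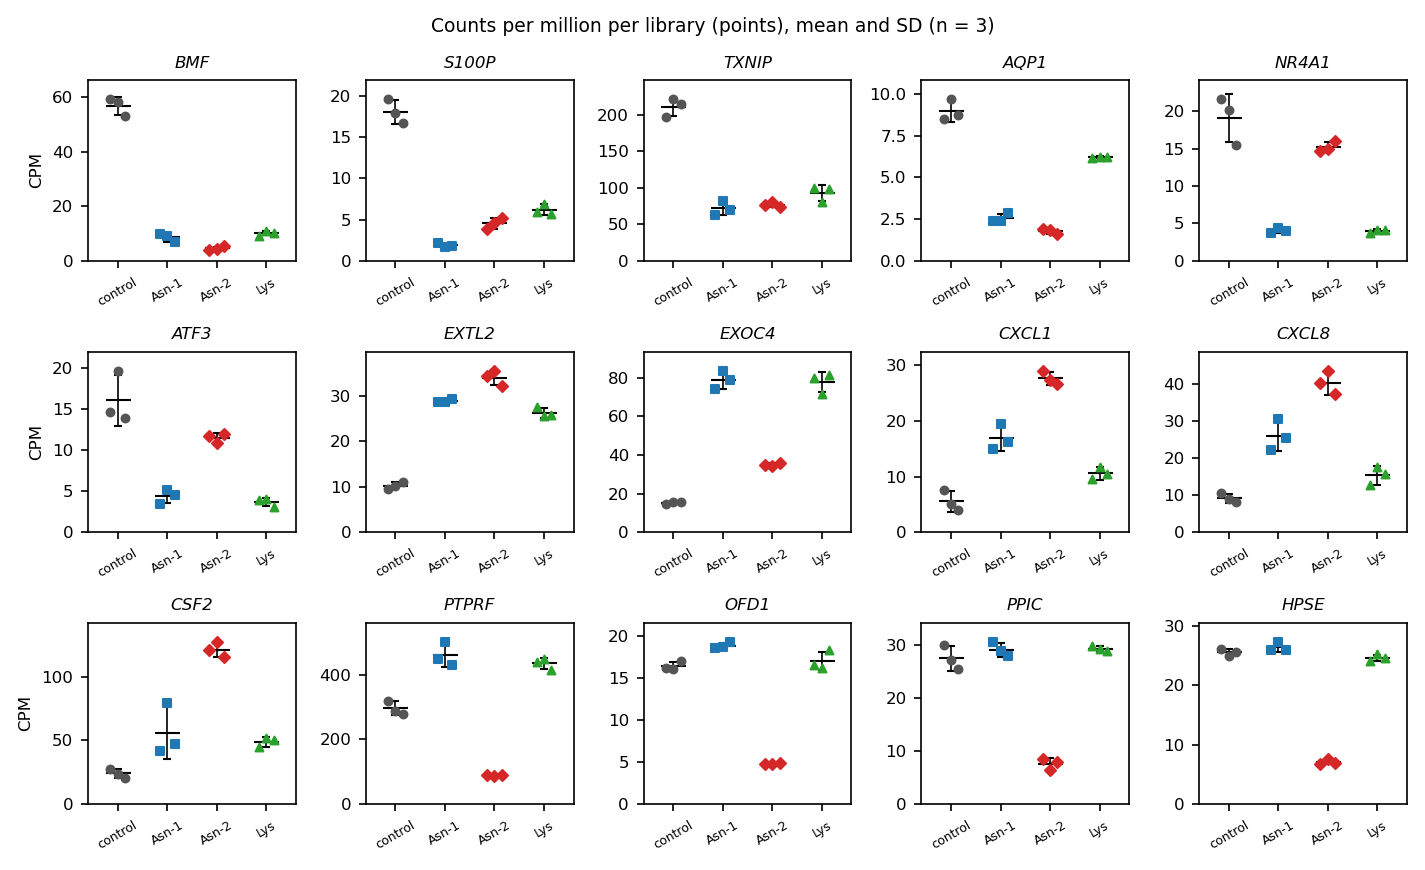
CPM of 15 named genes in each library (points) with the mean and SD (n = 3) for control, mtAsn-1, mtAsn-2 and mtLys LNA; the vertical axes start at 0. BMF, S100P and TXNIP are lower with each LNA than in control; PTPRF, OFD1, PPIC and HPSE are lowest with mtAsn-2.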

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

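Thinning of the libraries, the separate results of mtAsn-1 and of mtAsn-2 against mtLys, and the test on genes that did not differ between LNAs were chosen after the results were seen. The LNA groups differed from each other when tested directly by edgeR: 7465 genes between mtAsn-1 and mtAsn-2, 7807 between mtAsn-2 and mtLys, and 845 between mtAsn-1 and mtLys. The last count was 558 without mtAsn-1 replicate 1, 501 without mtAsn-1 replicate 2, 404 without mtLys replicate 2 and 417 without mtLys replicate 3. Genes that moved in opposite directions against control and differed between the groups numbered 760 for mtAsn-1 and mtAsn-2, 762 for mtAsn-2 and mtLys, and 19 for mtAsn-1 and mtLys. These were all the genes that moved in opposite directions, so the direct test removed none and adds no separate support. By camera 11 lists differed between mtAsn-1 and mtAsn-2, 12 between mtAsn-1 and mtLys, and 13 between mtAsn-2 and mtLys. With an estimated correlation 0 of these differed, where 5, 4 and 6 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list change at all, called 17, 6 and 21 of the 27 lists tested. Groups of 3 libraries were not tested for outlying samples.

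The first pattern weighed is that mtAsn-1 and mtLys libraries resembled each other more than mtAsn-1 and mtAsn-2, with 8.83 times as many genes called between the asparagine LNAs. A difference in depth as the whole cause is argued against, since the ratio was 9.26 with every library thinned to the smallest total. An exchange of the mtAsn-2 and mtLys labels cannot be told apart from the design as labelled: the MT-TN rate in mtAsn-1 and mtLys over that in control and mtAsn-2 was 1.29 (95% counting interval 0.627 to 2.68), from 19 and 16 reads. A difference between the oligonucleotides themselves remains open and untested.

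The second pattern is the 442 genes at least 2-fold lower with mtAsn-2 than with mtLys, among 719 at least 2-fold different either way (201 under the stricter filter on low counts). GC content or transcript length as the whole cause is argued against, because 87.8% of those with a transcript (330 of 376) stayed at least 2-fold lower once the trend was removed. Pairing of the LNA with transcripts that carry part of the MT-TN sequence cannot be told apart from other causes: the lowest median log2 change over 61 windows of 10 bases was -0.194 (permutation p = 0.18 over windows), introns were not searched, and the LNA sequences are not given in the sources used here.

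The third pattern is the 1730 genes that rose and 2042 that fell with all 3 LNAs against control, where independent lists would share 231 and 251. Noise of the shared control libraries as the whole cause is argued against only where it has the size of the spread between libraries of a group. With that spread, 20 simulations of unchanged groups gave at most 1 such gene. These simulations held no changed genes, so they do not show how far shared noise adds to the overlap among genes that do change. A shift common to all 3 control libraries was not simulated and stays open. An effect of the control LNA as the whole cause is argued against for the 53.92% of these genes that differed between at least a pair of LNA groups. That share rests largely on mtAsn-2: 6.18% differed between mtAsn-1 and mtLys, and 32.21% of the 326 genes changed at least 2-fold in all 3 differed between any pair, so the control LNA stays open as a source of much of the change. For the other 1738 genes, whose 3 log2 fold changes had a median range of 28.8% of their mean, an effect of the control LNA cannot be told apart from a shared effect of the tRNA LNAs, because no untransfected or second control group is in the design.

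Other splits of the libraries were refitted with the compared groups alone. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.1. The real split called 7265 genes for mtAsn-1 against control, 8124 for mtAsn-2 against control, 7949 for mtLys against control, 7199 for mtAsn-1 against mtAsn-2, 888 for mtAsn-1 against mtLys and 8126 for mtAsn-2 against mtLys. In each, 1 split called as many and the highest of the others called 0 by edgeR (at an unadjusted p under 0.05, 242, 271, 263, 292, 841 and 228). For the comparisons of both asparagine LNAs, the splits treated these LNAs as 1 group, so that the difference between them counted as spread. The real split then called 4281 genes against control and 49 against mtLys, where the fit with a mean for each LNA called 8042 and 4704. Against control, 1 of 84 splits called as many as the real 4281. The highest other, which set mtAsn-2 apart, called 3664, so the first place of the real split rests on the structure of the groups. Only 3 of the 84 splits keep the groups whole, and 3 splits cannot give a share under 0.05, so chance can be excluded only as a grouping that breaks up the LNA groups. Against mtLys, 2 of 84 splits called as many as the real 49. The other, which set mtAsn-2 apart, called 7809, so the libraries have a structure larger than the comparison.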

How the results depend on the processing

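Thinning of libraries, and mtAsn-1 and mtAsn-2 against mtLys as separate results with their alternatives, were chosen after the results were seen. Counts of genes past the threshold stayed within 1.5 times the reported count under RLE factors, DESeq2, both filters, factors without mitochondrial genes and thinning, and so did those of single comparisons in the compared groups alone, which was not run for the shared counts. Without a filter the balance of genes higher and lower turned, and the cause was not tested: 3862 and 4337 became 4268 and 3955 (mtAsn-2 against control), 3949 and 3516 became 3521 and 3823 (mtAsn-1 against mtAsn-2), and 3682 and 4125 became 3924 and 3866 (mtAsn-2 against mtLys). In the compared groups alone mtAsn-2 against control gave 4072 and 4052. For mtAsn-1 against control the 3901 and 3886 turned without control replicate 3 (3638 and 3690, the widest), any mtAsn-2 replicate or mtLys replicate 3. Counts of genes at least 2-fold different did not stay within that range under the stricter filter, which tests fewer genes: 920 became 199 (mtAsn-1 against control), 963 became 223 (mtAsn-2), 909 became 172 (mtLys), 745 became 139 (both asparagine LNAs), 152 became 19 (these against mtLys), 687 became 186 (between them) and 719 became 201 (mtAsn-2 against mtLys). For both asparagine LNAs against mtLys, DESeq2 gave 94 and no filter 254, and the cause was not tested. Leaving out single libraries gave 6737 to 7898 genes for mtAsn-1 against control, 7457 to 8524 for mtAsn-2, 6758 to 8167 for mtLys, 6971 to 8062 for both asparagine LNAs, 3584 to 4908 for these against mtLys, 6480 to 7560 between them, 6830 to 8122 for mtAsn-2 against mtLys and 3755 to 4353 shared by both. The 188 genes shared by both asparagine LNAs and differing from mtLys ranged from 108 to 191 (124 without mtAsn-1 replicate 2, 110 without mtLys replicate 2, 108 without mtLys replicate 3), and the higher ones among them changed further, from 60 to as few as 26 without mtLys replicate 2. The 845 genes between mtAsn-1 and mtLys ranged from 404 to 922 (558 and 501 without mtAsn-1 replicates 1 and 2, 404 and 417 without mtLys replicates 2 and 3). These fits had fewer samples. Of 60 list calls by camera, 0 were called with an estimated correlation, where 23 had an unadjusted p under 0.05. Against the preset 0.01, the estimates for mtLys against control were 0.533 for ribosomal protein genes and 0.343 for NF-kB targets. They were 0.153 for ATF4 targets, 0.0156 for serine, glycine and folate genes, and -0.0092 for leukocyte markers. The preset test thus took genes of all but the last list as less correlated than estimated, and the last lost its call too. For leukocyte markers the unadjusted camera p went from 0.00918 to 0.0284, though the estimate was below the preset value. For serine, glycine and folate genes it went from 0.00755 to 0.0346. The settings thus differ in more than the correlation, and the lost calls cannot be put down to correlated genes alone. Fry gave 103 calls, adding 47 and losing 4. Its counts answer another question than those of camera, whether the genes of a list change at all. No other cause of the difference was tested. Of 659 named gene results, 597 kept their side of the threshold under every alternative that tested them, 62 did not under at least 1, and 0 reversed. The stricter filter left 23 of them untested, thinning 4 and the compared groups alone 1. Replicate numbers did not pair libraries (18 correlations, -0.099 to 0.042), and a replicate block left the counts within 1.5 times. Depth limits MT-TN, with at most 6 reads per library.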

Other observations

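The comparisons in this part were made separate results, and the genes chosen, after the data had been seen. Set directly against mtLys, mtAsn-1 differed in 845 genes by edgeR (n = 3 each), a count that was 558 without mtAsn-1 replicate 1, 501 without mtAsn-1 replicate 2, 404 without mtLys replicate 2 and 417 without mtLys replicate 3. S100P (-1.71 ± 0.151, adjusted p = 1.5e-08), CEMIP (-1.36 ± 0.0893), AQP1 (-1.27 ± 0.124), the interleukin receptor gene IL7R (-0.98 ± 0.0969) and the secretory protein gene AGR2 (-0.97 ± 0.0708) were lower with mtAsn-1, and NUPR1 (0.77 ± 0.146) and CXCL8 (0.76 ± 0.139) were higher. With mtAsn-1, NUPR1 was at 5.65 CPM, still below the 15.7 CPM of control. Of 69 cytosolic ribosomal protein genes, 32 were higher and 0 lower (57 and 0 adjusted over the list alone; camera adjusted p = 4.49e-35, and adjusted p = 0.24 with an estimated correlation). Of 35 interferon-stimulated genes, 13 were lower and 0 higher (18 and 0 adjusted over the list alone; camera 7.19e-13, and adjusted p = 0.109 with an estimated correlation), with ISG20 at -0.47 ± 0.0746. Of 31 ATF4 targets, 13 were higher and 0 lower (15 and 1 adjusted over the list alone; camera 5.69e-12, and adjusted p = 0.109 with an estimated correlation), PSAT1 by 0.37 ± 0.0584. Mitochondrial tRNA and rRNA genes were called lower by camera (adjusted p = 0.0154, and 0.553 with an estimated correlation), with 1 of 18 lower and 0 higher. Replication-dependent histones were called lower too (camera adjusted p = 0.0316, and 0.553 with an estimated correlation), with 3 of 16 lower and 0 higher. Against mtLys, camera called neither list with mtAsn-2 (adjusted p = 0.465 and 0.132).

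Against mtLys, mtAsn-2 gave 3682 genes higher and 4125 lower by edgeR (3924 and 3866 without a filter). PTPRF (-2.30 ± 0.0555, adjusted p = 2.67e-19), AQP1 (-1.80 ± 0.121), COL5A1 (-1.25 ± 0.0429) and BMF (-1.15 ± 0.117) were lower, and CXCL2 (1.90 ± 0.129), PHGDH (1.15 ± 0.0766), TRAF1 (0.96 ± 0.068) and NFKB2 (0.94 ± 0.0451) were higher. Glycolysis genes were lower, 19 of 22 with 1 higher (19 and 1 adjusted over the list alone; camera 2.1e-08, and adjusted p = 0.124 with an estimated correlation), and NF-kB targets were higher, 21 of 22 with 0 lower (21 and 0 adjusted over the list alone; camera 1.96e-15, and adjusted p = 0.124 with an estimated correlation). Interferon-stimulated genes, which were lower with mtAsn-1, were higher with mtAsn-2, 19 of 35 with 4 lower (19 and 4 adjusted over the list alone; camera 1.56e-04, and adjusted p = 0.22 with an estimated correlation).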
